A study of Homo sapiens with 6 samples.

How the data were processed

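Gene expression was measured by RNA sequencing in 6 libraries of A549 cells, 3 given PQ and 3 given PQ with SS-31, all labelled 48 h. The dose of either agent is not given in the sources used here. The authors deposited raw counts per gene for the 6 libraries in 1 table of 58735 genes, and the values are whole numbers that sum to 16332061 to 17576827 per library. Reads were handled with CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, per the submitters' processing notes. Those notes name the mouse build mm10, but all 58735 deposited gene IDs are human and match GENCODE 29, on GRCh38, in chromosome, start, end and strand, so coordinates are given on GRCh38. Whether the library kit marks strand, and whether counting used it, is not given in the sources used here, so overlapping and antisense genes are not told apart. Reads shared between near-identical copies can be split or lost in such counts, which applies to HSPA1B and to the pseudogene RPLP0P2. Columns were assigned to samples by the group letter and replicate number in their names, matched to the titles, and 0 columns of sample values were left out.

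Counts were filtered with edgeR's filterByExpr by group, which kept 15550 genes, and scaled with TMM factors. PQ+SS-31 was compared with PQ by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Group levels are TMM-scaled CPM, counts relative to the library total, as mean ± SD over 3 libraries, and log2 fold changes are fitted values with SE derived from the test statistic. Gene lists, 27 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members, with adjustment over the lists, and again with an estimated correlation and with fry. Of 1040 listed symbols, 1038 matched a gene ID. The histone list gives older and current symbols of the same genes, so its 76 symbols stand for 54 genes in the table. Shares of counts were compared by an exact two-sided permutation test over the 20 assignments of 3 and 3, whose smallest p is 0.1. The groups, tests, lists, the rule for named genes and the alternatives, apart from those named below as later choices, were fixed before the data were examined.

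Named genes are, first, the 8 largest rises and 8 largest falls among protein-coding genes with adjusted p under 0.05, a mean of at least 5 CPM and groups that do not overlap. They are, next, the members with the smallest p from each list, up to 4 for the MAPK core kinases, MAPK output, NF-kB, mesenchymal and mitochondrially encoded lists and up to 2 for every other list, where a list with no member past the threshold may be given by its count alone. MAPK3, MAPK8, MAPK9 and MAPK14 were named in any case. Some genes that the rule names are not reported here. The alternatives were RLE and upper-quartile factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, protein-coding genes alone, DESeq2 1.42.0, limma-voom, a log2 fold change of at least 1, glmTreat against 1.2-fold, and leaving out each library. Chosen after seeing the data were leaving out mitochondrial genes, and per-library offsets for GC content and transcript length (loess, span 0.5) with and without the block; 15541 of the 15550 tested genes had both properties.

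On simulated counts drawn from the means and library sizes of this comparison, with 15550 genes, edgeR recovered 46 of 100 genes changed 1.5-fold and 89 of 100 changed 2-fold, and 6 of its 141 calls were unchanged genes. Changes of 1.5-fold were therefore often missed in these simulated counts, with 3 libraries per group at this depth. Smaller changes of single genes were not scored. The changed genes were drawn from those with a mean of at least 5 CPM. Counts were drawn separately for each gene, without structure shared between genes. The 6 unchanged calls therefore do not give the rate of false calls in the real data. Pairs of libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom from 7.337 to 35.62, so all 6 libraries were counted.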

Results

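RNA sequencing measured gene expression in 6 libraries of A549 cells, a human lung adenocarcinoma line that the labels describe as alveolar epithelial. The libraries fell into 2 groups of 3, both labelled 48 h: cells given paraquat (PQ), a herbicide that generates superoxide by redox cycling, and cells given PQ with SS-31, a mitochondria-targeted peptide that binds cardiolipin. Total counts per library ranged from 16332061 in PQ replicate 3 to 17576827 in PQ+SS-31 replicate 3. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No untreated library was analysed here, so the effect of PQ itself was not measured. The first principal component, with 39.4% of the variance of log-CPM, ran within the groups, with PQ replicate 3 and PQ+SS-31 replicates 1 and 3 on one side and the other libraries on the other. The second component, with 23.5%, separated the groups. The long non-coding RNA NEAT1 stood at 884.5 CPM in PQ replicate 3, against 220.3 and 151.9 CPM in PQ replicates 1 and 2, and at 364.5, 200.2 and 437 CPM in PQ+SS-31 replicates 1, 2 and 3. Its highest levels were in the 3 libraries on one side of the first component.

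The comparison of PQ+SS-31 with PQ asked which transcripts SS-31 altered in PQ-treated cells, with the MAPK pathway named in the series title. Genes lower with SS-31 included 5 of 38 tested genes of MAPK output, 5 of 41 of NF-kB and inflammation and 4 of 36 of the ATF4 stress response, and genes higher with SS-31 included 7 of 46 of G2/M. The first 3 lists passed camera with a preset correlation but not with an estimated correlation (adjusted p = 0.181, 0.406 and 0.242 with an estimated correlation). The G2/M list passed with both. The heat shock gene HSPA6 showed the largest fall among the genes named here, from 12.9 ± 2.86 CPM (SD, n = 3) to 1.43 ± 0.344 CPM (SD, n = 3), which is 9.04-fold. DUSP5, a phosphatase that inactivates ERK in the nucleus, fell from 326 ± 8.34 to 162 ± 7.59 CPM. CDH1, the epithelial adhesion protein E-cadherin, rose from 13.6 ± 1.40 to 24.4 ± 3.12 CPM, and CDK1, the kinase that drives entry into mitosis, rose from 39.5 ± 1.02 to 59.4 ± 1.06 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 20 of 15550 tested genes were higher and 72 lower with SS-31, and 14 of these, all lower, changed by at least 1 on the log2 scale. In each of the 92 genes all 3 libraries of a group lay above the 3 of the other. This separation was seen in 2802 tested genes (18.02%). Chance gives 10% as an average over all splits of the libraries. Genes are not independent, so the share in any given split can lie far from that average. The share was not computed for the other splits, so no excess over chance is read from it.

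These counts moved with each library left out. They dropped without 5 of the 6 and grew without PQ replicate 3. Refits have fewer libraries, so a gene that misses the threshold in a refit need not have changed less. Refits with edgeR gave 0 higher and 1 lower without PQ replicate 1, 0 and 10 without PQ replicate 2, and 125 and 203 without PQ replicate 3. They gave 0 and 5 without PQ+SS-31 replicate 1, 0 and 1 without PQ+SS-31 replicate 2, and 0 and 0 without PQ+SS-31 replicate 3, where 597 and 659 genes passed an unadjusted p of 0.05. DESeq2 called 115 higher and 188 lower, and offsets for GC content and transcript length, chosen after seeing the data, gave 99 and 173. The share of higher genes among the calls also depended on these settings.

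**Figure D1:**
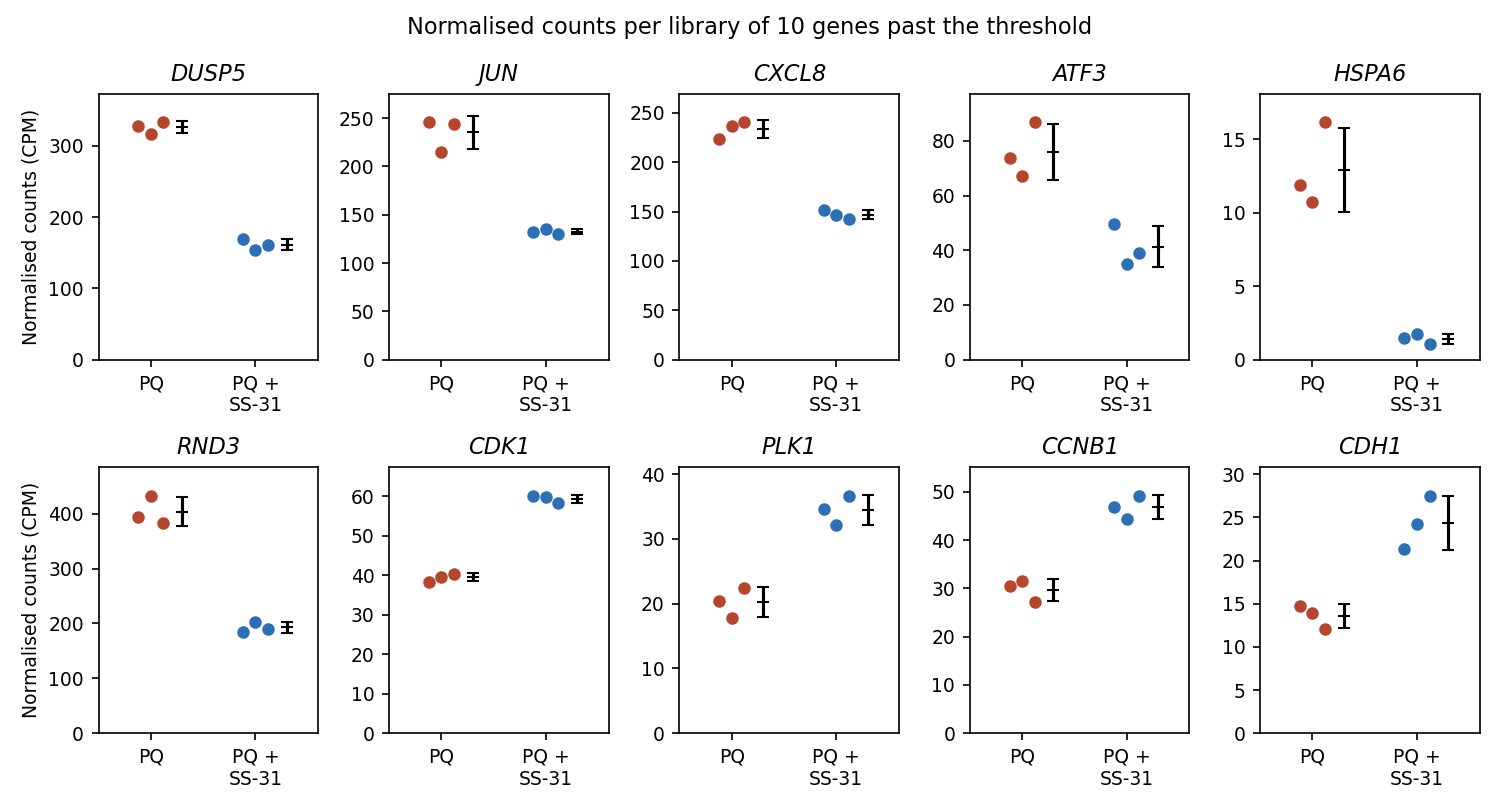
Normalised counts (CPM, y axes from 0) of 10 genes past the threshold in each PQ library (red points) and PQ+SS-31 library (blue points), with the mean and SD of the 3 libraries in black. The groups do not overlap in any panel; DUSP5 averages 326 CPM with PQ and 162 CPM with PQ+SS-31.

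The largest falls among protein-coding genes of at least 5 CPM were those of HSPA6, HK2, N4BP3, GEM, IGFBP1, CORO2B, RND3 and NR1D1. HSPA6 (chromosome 1, 161524540 to 161526910, GRCh38) changed by -3.18 ± 0.24 on the log2 scale (SE), with an edgeR adjusted p of 0.00398, and passed the threshold in 5 of the 6 refits without 1 library. The other falls listed here passed in 1 to 3 of the 6. RND3, an atypical small GTPase (chromosome 2, 150468195 to 150539011), fell from 404 ± 26.2 to 193 ± 9.46 CPM (log2 fold change -1.07, edgeR adjusted p = 0.00398). GEM, a small GTPase of the RGK family, fell from 38.6 ± 3.07 to 17.1 ± 0.615 CPM, and N4BP3 from 27.7 ± 0.605 to 12.1 ± 1.25 CPM. IGFBP1, a secreted binder of insulin-like growth factors, fell from 26.6 ± 5.13 to 11.9 ± 1.07 CPM. CORO2B, an actin-binding coronin, fell from 9.68 ± 0.943 to 4.32 ± 0.927 CPM. NR1D1, the circadian repressor REV-ERBα, fell from 47.4 ± 5.78 to 23.1 ± 3.82 CPM. The largest rises were those of CDH1, KIF20A, PLK1, CDKN2C, FGA, SAMD11, CCNB1 and DLGAP5, from 0.84 down to 0.65 on the log2 scale. Of these, KIF20A, PLK1, CCNB1 and DLGAP5 act in mitosis. Each of the listed rises passed the threshold in 1 of the 6 refits without 1 library. CDKN2C, an inhibitor of CDK4 and CDK6, rose from 13.7 ± 0.635 to 23.0 ± 0.862 CPM, and FGA, the fibrinogen alpha chain, from 20.8 ± 2.89 to 33.4 ± 1.24 CPM.

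The list of genes induced by MAPK signalling passed in the lower direction by camera with a preset correlation, not with an estimated one. It also passed by fry (adjusted p = 0.0187), which tests whether members move one way and compares them with no other genes. Of 38 tested members of the MAPK output list, 5 fell and 0 rose, and 9 fell when adjusted over the list alone. The median log2 fold change was -0.25, with 34 members negative (camera with a preset correlation, adjusted p = 2.31e-09; adjusted p = 0.181 with an estimated correlation). DUSP5 (chromosome 10, 110497838 to 110511544) changed by -1.01 ± 0.08 (SE). JUN, a subunit of the transcription factor AP-1 (chromosome 1, 58780788 to 58784327), fell from 235 ± 17.5 to 132 ± 2.74 CPM. DUSP6, a cytoplasmic ERK phosphatase (chromosome 12, 89347232 to 89353271), fell from 22.2 ± 1.005 to 12.6 ± 1.01 CPM. EREG, a ligand of the EGF receptor, fell from 742 ± 53.4 to 489 ± 31 CPM. Other immediate-early genes of the list, FOS, FOSB, EGR1, IER2 and JUNB, named after their values were seen, did not pass. The 4 members with positive log2 fold changes, also named afterwards, did not pass. They were SPRY1 (0.14), SPRED2 (0.14), ETV4 (0.12) and ETV5 (0.07). The kinases themselves were tested as a separate list of 42 genes, of which edgeR called 0 in either direction, also when adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p of 0.05. DESeq2 called 0 higher and 1 lower and limma-voom 0. The median of the kinase list was -0.04 (camera, adjusted p = 0.0796; adjusted p = 0.493 with an estimated correlation), and the list passed the threshold in the lower direction without PQ replicate 3 (camera, adjusted p = 0.0127, over refits without 1 library 0.0127 to 0.282). The log2 fold changes were 0.22 ± 0.10 for MAPK3 (ERK1), -0.13 ± 0.09 for MAPK8 (JNK1), 0.05 ± 0.08 for MAPK9 (JNK2) and -0.04 ± 0.09 for MAPK14 (p38α), given with SE, and none passed the threshold. These are transcript levels; phosphorylation was not measured here.

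The inflammatory list passed in the lower direction by camera with a preset correlation, and not by fry (adjusted p = 0.138). In the list of NF-kB targets and cytokines, 5 of 41 tested genes fell and 0 rose, against 8 and 4 when adjusted over the list alone, with a median of -0.19 (camera, adjusted p = 7.39e-04; adjusted p = 0.406 with an estimated correlation). PQ+SS-31 replicate 1 lay above PQ replicates 1 and 2 in the median deviation of this list (0.103 against 0.0831 and -0.0188 on the log2 scale). CXCL8, the neutrophil chemokine interleukin-8 (chromosome 4, 73740506 to 73743716), fell from 234 ± 9.31 to 147 ± 4.27 CPM. RELB, a subunit of non-canonical NF-kB, fell from 106 ± 4.90 to 71.1 ± 4.70 CPM. PTGS2, the inducible prostaglandin synthase COX-2, fell from 249 ± 7.68 to 175 ± 4.81 CPM, and IRAK2, a kinase of Toll-like and interleukin-1 receptor signalling, from 143 ± 11.1 to 90.5 ± 9.88 CPM. Interferon-stimulated genes moved the other way as a list, with a median of 0.14 over 39 genes and 31 members positive (camera, adjusted p = 0.00330; adjusted p = 0.150 with an estimated correlation). The only member called by edgeR, RSAD2 (viperin), went against the list and fell from 113 ± 7.75 to 79.3 ± 0.536 CPM, while HERC5, an ISG15 ligase, was at 204 ± 7.58 and 270 ± 8.64 CPM without passing over all genes. Adjusted over the list alone, 1 member was higher and 1 lower.

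Among the stress-response lists, that of ATF4 targets passed in the lower direction by camera with a preset correlation and by fry (adjusted p = 0.0369). Those of ER chaperones and heat shock did not pass. Of 36 targets of ATF4 and the integrated stress response, 4 fell and 0 rose, or 7 and 0 adjusted over the list alone (median -0.08; camera, adjusted p = 0.0149; adjusted p = 0.242 with an estimated correlation). Among them, TRIB3, a pseudokinase induced by ATF4, fell from 292 ± 11.5 to 196 ± 5.23 CPM and ATF3, a stress-induced transcription factor, from 76.0 ± 10.1 to 41.3 ± 7.44 CPM. The list of ER chaperones did not pass (median 0.02 over 26 genes; camera, adjusted p = 0.371), with 0 higher and 1 lower over all genes and 2 and 2 adjusted over the list alone. Its members split: ERN1, the ER stress sensor IRE1α, fell from 67.0 ± 5.13 to 41.6 ± 3.20 CPM, while PDIA4, an ER disulfide isomerase, was at 252 ± 8.15 and 349 ± 19.9 CPM without passing over all genes. In the heat shock list, 1 of 21 genes fell, or 4 adjusted over the list alone, with a median of 0.00 and a mean of -0.07, which differ in sign (camera, adjusted p = 0.155). The list as fixed does not hold HSPA6, which fell, or HSPA2, an HSP70 relative named after its values were seen, which rose from 68.8 ± 4.64 to 97.3 ± 3.64 CPM. HSPA1B, an inducible HSP70, fell from 32.0 ± 4.001 to 19.2 ± 1.92 CPM, a value left uncertain because its sequence is nearly identical to that of HSPA1A. DNAJB1, a co-chaperone of HSP70, was at 114 ± 5.21 and 88.1 ± 5.13 CPM and did not pass.

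Autophagy and lysosome genes had a median of -0.07 over 38 genes (camera, adjusted p = 0.0128; adjusted p = 0.242 with an estimated correlation), and 1 fell, or 4 adjusted over the list alone. The call was lost without PQ replicate 3 (camera, adjusted p = 0.0847) and without PQ+SS-31 replicate 2 (0.0745), in a range of 0.00611 to 0.0847. SQSTM1, the autophagy receptor p62 (chromosome 5, 179806398 to 179838078), fell from 1350 ± 43.3 to 739 ± 13.03 CPM. Targets of p53 had a median of -0.10 over 34 genes (camera, adjusted p = 0.00827; adjusted p = 0.242 with an estimated correlation), with 0 single genes called by edgeR, also when adjusted over the list alone, 7 lower at an unadjusted p of 0.05, 1 lower by DESeq2 and 0 by limma-voom. Apoptosis regulators had a median of -0.09 over 34 genes (camera, adjusted p = 0.0391; adjusted p = 0.332 with an estimated correlation), with 0 called over all genes by edgeR and 2 lower adjusted over the list alone, which were the pro-apoptotic BMF and HRK. At an unadjusted p of 0.05, edgeR had 1 higher and 5 lower, and DESeq2 called 2 lower and limma-voom 1. The apoptosis list missed the threshold without PQ replicate 1 (camera, adjusted p = 0.188), PQ replicate 3 (0.0591) or PQ+SS-31 replicate 3 (0.0579), in a range of 0.014 to 0.188.

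Targets of the oxidative stress factor NRF2 had a median of 0.11 over 38 genes, with 28 members positive and 10 negative (camera, adjusted p = 0.0219; adjusted p = 0.181 with an estimated correlation). Of the 38, 1 was higher and 0 lower, or 5 and 2 adjusted over the list alone. The call was lost without PQ replicate 3 (camera, adjusted p = 0.141) and without PQ+SS-31 replicate 2 (0.0564), in a range of 0.0165 to 0.141. In refits without 1 library, 1 to 4 members were higher and 0 to 3 lower adjusted over the list alone. ALDH3A1, an aldehyde dehydrogenase, rose from 649 ± 29.9 to 995 ± 61.3 CPM. NR0B1, a nuclear receptor in the same list, was at 32.1 ± 2.30 and 22.0 ± 2.17 CPM and did not pass. OSGIN1 and HMOX1 of this list, named after their values were seen, had log2 fold changes of -0.50 and -0.30 and did not pass over all genes. Antioxidant enzymes had a median of 0.10 over 26 genes (camera, adjusted p = 0.0814), with 0 called by edgeR, DESeq2 or limma-voom and 4 higher and 1 lower at an unadjusted p of 0.05; the list passed without PQ+SS-31 replicate 2 (camera, adjusted p = 0.0426) or 3 (0.0165), in a range of 0.0165 to 0.793.

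Both cell cycle lists rose. In the G2/M list all 46 tested genes had positive log2 fold changes with a median of 0.45. Of these, 7 rose and 0 fell, or 33 and 0 adjusted over the list alone (camera, adjusted p = 4.21e-24; adjusted p = 0.0279 with an estimated correlation). KIF20A, a kinesin of cytokinesis, rose from 11.4 ± 0.986 to 20.2 ± 0.775 CPM, PLK1, a mitotic kinase, from 20.2 ± 2.29 to 34.4 ± 2.31 CPM, and CCNB1, cyclin B1, from 29.7 ± 2.22 to 46.8 ± 2.45 CPM. The G1/S list had a median of 0.31 with 40 of 43 members positive; 1 rose and 0 fell, or 23 and 0 adjusted over the list alone (camera, adjusted p = 2.78e-16; adjusted p = 0.0145 with an estimated correlation). TK1, the thymidine kinase of S phase, rose from 47.7 ± 0.550 to 65.7 ± 2.15 CPM, and MCM7, a subunit of the replicative helicase, was at 97.7 ± 4.13 and 135 ± 7.40 CPM without passing over all genes. These were the only lists past the threshold with an estimated correlation. In refits without 1 library, 10 to 23 genes of the G1/S list were higher adjusted over the list alone. Replication-dependent histone genes, which are transcribed in S phase, had a median of -0.31 over 16 genes (camera, adjusted p = 7.57e-04; adjusted p = 0.478 with an estimated correlation). These 16 are those of 54 histone genes in the table that passed the filter on low counts. The library kit is not given, so how fully it captured histone transcripts is not known. The histone call was lost without PQ replicate 3, with a median of -0.16 (camera, adjusted p = 0.0883, in a range of 6.77e-06 to 0.0883). By edgeR 0 histone genes were called, 3 were lower at an unadjusted p of 0.05 and 1 adjusted over the list alone, and DESeq2 called 1 lower and limma-voom 0.

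Mitochondrial transcripts showed small differences. Nuclear-encoded OXPHOS subunits had a median of 0.13 with 69 of 75 members positive (camera, adjusted p = 5.99e-05; adjusted p = 0.493 with an estimated correlation), but edgeR called 0 of them, with 6 higher at an unadjusted p of 0.05 and 0 by DESeq2 or limma-voom. Without PQ+SS-31 replicate 1 the median was 0.04 and the call was lost (camera, adjusted p = 0.0715, in a range of 6.01e-08 to 0.0715). The 13 mitochondrially encoded proteins had a median of 0.14 (camera, adjusted p = 0.292), with 0 called by edgeR, 0 at an unadjusted p of 0.05 and 0 by DESeq2 or limma-voom; the list passed without PQ replicate 2 (camera, adjusted p = 0.041) or PQ+SS-31 replicate 1 (1.01e-05), in a range of 1.01e-05 to 0.972. Genes of mitochondrial biogenesis, dynamics and cardiolipin synthesis had a median of 0.00 over 36 genes (camera, adjusted p = 0.984), with 0 called by edgeR, DESeq2 or limma-voom and 1 lower at an unadjusted p of 0.05. Mitochondrial genes held 10.3 ± 1.47% of counts with PQ and 11.2 ± 2.45% with PQ+SS-31 (SD, n = 3, exact two-sided permutation p = 0.6, where 3 against 3 cannot go below 0.1).

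Epithelial and mesenchymal lists did not pass. Of 25 genes of epithelial adhesion and keratins, CDH1 rose, and 4 were higher and 2 lower adjusted over the list alone (median 0.16; camera, adjusted p = 0.159); the list passed without PQ+SS-31 replicate 1 (camera, adjusted p = 0.0476, in a range of 0.0476 to 0.684). KRT18, a keratin of simple epithelia, was at 408 ± 8.67 and 562 ± 48.5 CPM without passing over all genes. Of 58 mesenchymal and extracellular matrix genes, SNAI2, the transcription factor SLUG that represses CDH1, fell from 11.9 ± 0.608 to 6.53 ± 0.638 CPM. It was the only call also when adjusted over the list alone (median -0.02; camera, adjusted p = 0.245). TNC, the matrix glycoprotein tenascin-C, was at 16.7 ± 2.93 and 11.4 ± 1.51 CPM and did not pass. Alveolar and airway markers had a median of 0.04 and a mean of -0.00, which differ in sign, over 12 tested genes (camera, adjusted p = 0.810), with 0 called by edgeR over all genes and 2 higher and 1 lower adjusted over the list alone.

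In the list of glycolysis and hypoxia genes 3 of 38 fell, or 6, with 4 higher, adjusted over the list alone (median -0.05; camera, adjusted p = 0.357). HK2, a hexokinase of the first step of glycolysis, fell from 20.7 ± 2.17 to 7.91 ± 1.89 CPM and NDRG1, a hypoxia-induced gene, from 179 ± 9.82 to 99.9 ± 1.69 CPM. PLIN2, a lipid droplet coat protein, fell from 114 ± 3.998 to 70.2 ± 4.29 CPM, while its list of fatty acid genes did not pass (median 0.08 over 24 genes; camera, adjusted p = 0.371; 2 higher and 1 lower adjusted over the list alone). Genes of cholesterol synthesis and SREBP2 had a median of 0.20 with 21 of 25 members positive (camera, adjusted p = 3.01e-04; adjusted p = 0.150 with an estimated correlation), and edgeR called 0 of them, with 10 higher and 1 lower at an unadjusted p of 0.05 and 0 by DESeq2 or limma-voom. The list of metallothioneins, iron and ferroptosis (22 genes, median -0.09; camera, adjusted p = 0.147) held 1 call, PTGS2, also when adjusted over the list alone. The 77 cytosolic ribosomal protein genes had a median of 0.01 (camera, adjusted p = 0.810) with 0 called by edgeR, DESeq2 or limma-voom and 0 at an unadjusted p of 0.05, and the list passed in the lower direction without PQ+SS-31 replicate 1 (camera, adjusted p = 0.00147, in a range of 0.00147 to 0.837).

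Most markers of other cell types were too low to test. Of 24 leukocyte, endothelial, fibroblast and erythroid genes, 5 were abundant enough to test, with a median of 0.42 (camera, adjusted p = 0.0112; adjusted p = 0.193 with an estimated correlation) and 2 higher adjusted over the list alone. LUM, the matrix proteoglycan lumican, was at 0.800 ± 0.172 and 1.83 ± 0.379 CPM and CD14, a co-receptor for lipopolysaccharide, at 4.31 ± 0.727 and 6.30 ± 0.416 CPM, and neither passed over all genes. Ribosomal protein genes held 3.85 ± 0.314% and 3.83 ± 0.538% of counts (SD, n = 3, exact two-sided permutation p = 1), and the 50 most abundant genes 18.5 ± 1.37% and 19.6 ± 2.19% (SD, n = 3, exact two-sided permutation p = 0.6).

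**Figure D2:**
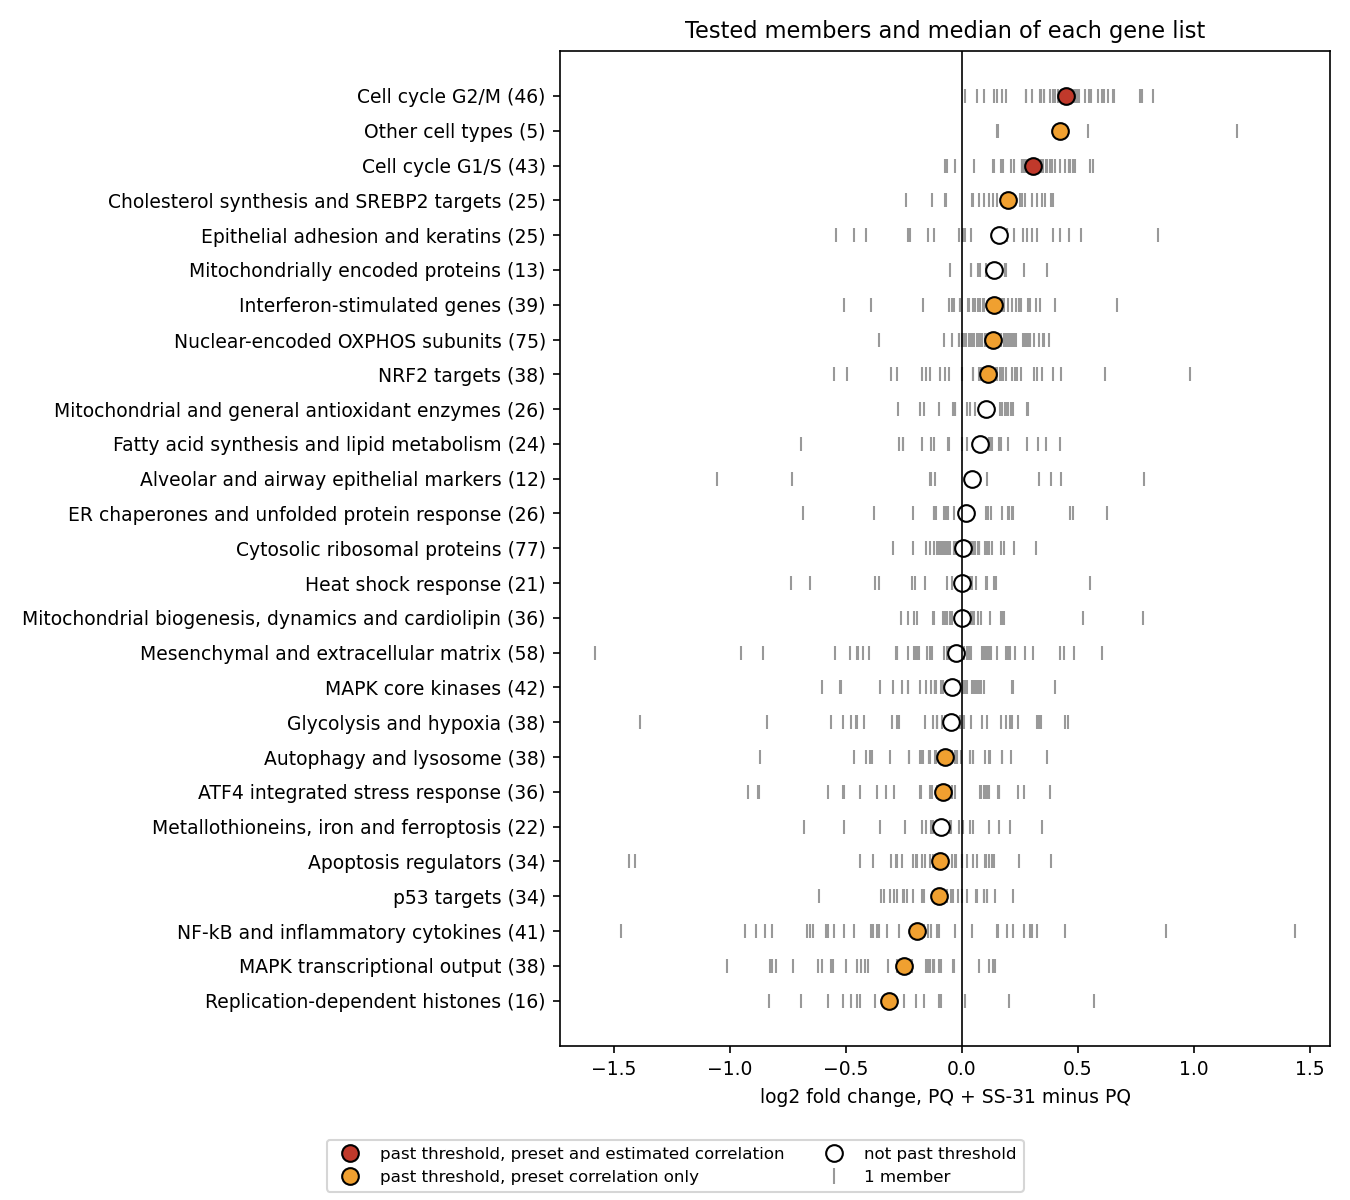
Log2 fold change (x axis, PQ+SS-31 minus PQ) of each tested member (grey marks) and the median (circles) of 27 gene lists, with the number of tested members in brackets; red circles passed camera's threshold with both a preset and an estimated correlation, orange circles with the preset correlation alone, white circles neither. The G2/M and G1/S lists, with medians of 0.45 and 0.31, are the red ones.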

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

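The offsets and the removal of mitochondrial genes were chosen after seeing the data, and the other alternatives before. Named genes and lists were compared for direction between the main fit to all 6 libraries and each alternative run for them. None that passed its threshold in either fit had opposite directions. Other called genes were not compared gene by gene. Between refits a list could still turn. The ribosomal protein list passed in the lower direction without PQ+SS-31 replicate 1 (camera, adjusted p = 0.00147). It pointed higher, without passing, without PQ+SS-31 replicate 3 (camera, adjusted p = 0.0639). Leaving out 1 library gave 0 to 125 genes higher and 0 to 203 lower, against 20 and 72 with all 6. Only without PQ replicate 3 did the counts grow (125 and 203, which include all 20 and 72). Without PQ+SS-31 replicate 3, 36 named genes missed the threshold, keeping their direction. Counts of higher and lower genes were 156 and 237 with no filter on low counts, 115 and 188 with DESeq2, 99 and 173 with the GC and length offsets, 0 and 14 with a log2 fold change of at least 1, and 0 and 12 with glmTreat; higher genes numbered 13 with library size alone and 36 with protein-coding genes alone. Apart from the 2 settings on effect size, the cause of these moves was not tested. RLE and upper-quartile factors, the 1 CPM filter, limma-voom and the removal of mitochondrial genes kept both gene counts within 1.5 times. The replicate block gave 66 and 134 genes, which include all 20 and 72, and 174 and 259 with the offsets added. Deviations of same-numbered libraries correlated at -0.0923, 0.392 and 0.191, and those of differently numbered libraries at -0.457 to 0.292. Not every sample correlated best with its own number. These mixed values cannot tell whether equal numbers mark a shared culture or day. Of 7 lists higher and 7 lower, 2 and 0 passed with an estimated correlation, and 5 and 4 with fry. Besides the cell cycle, MAPK output and ATF4 lists, fry passed NRF2, interferon-stimulated and cholesterol genes (each adjusted p = 0.00905). It also passed p53 targets (0.0424) and autophagy (0.0458). The called lists that missed with fry were NF-kB (adjusted p = 0.138), nuclear-encoded OXPHOS (0.291), histones (0.283), apoptosis (0.0855) and other cell types (0.0505). Leaving out 1 library gave 6 to 8 lists higher and 5 to 8 lower. With this depth and 3 libraries per group, changes of 1.5-fold were often missed in simulated counts, and smaller changes of single genes were not scored.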

Other observations

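The tests of a single library, of GC content and length, of a shift towards G2/M and of the clock were chosen after the results were seen; the splits of the samples were planned. Of the 92 called genes, 59 are in no list, and those named in the next paragraph were chosen after their values were seen.

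Single genes past the threshold outside the lists are given here, with no group tested. IGFBP3, a binder of insulin-like growth factors, fell from 319 ± 1.97 to 198 ± 14.6 CPM (SD, n = 3), the glycoprotein hormone STC1 from 184 ± 20.2 to 107 ± 6.11 CPM, SPP1 (osteopontin) from 99.0 ± 4.75 to 64.3 ± 5.45 CPM, and GREM1, a BMP antagonist, from 43.7 ± 0.348 to 29.8 ± 1.30 CPM. The transcription factor KLF6 fell from 146 ± 9.94 to 78.4 ± 4.49 CPM, KLF11 from 42.5 ± 2.29 to 20.8 ± 3.10 CPM and ETS1 from 117 ± 9.96 to 75.7 ± 2.08 CPM. SMAD6, an inhibitor of BMP signalling, rose from 61.3 ± 5.72 to 91.5 ± 2.62 CPM, and NNMT, a nicotinamide methyltransferase, from 72.6 ± 3.85 to 108 ± 1.70 CPM. The pseudogene RPLP0P2 fell from 6.36 ± 0.992 to 1.75 ± 0.235 CPM, a value left uncertain because it shares sequence with RPLP0.

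Other splits of the 6 libraries into 3 and 3 were fitted in the same way. The split by treatment called 92 genes, and the highest other split called 716, so 2 of the 10 splits gave at least 92. That split set PQ replicates 1 and 2 and PQ+SS-31 replicate 2 against the rest, the same division as the first principal component, and it calls several times the real count, so the samples hold a structure other than treatment that is larger by this measure. The loadings of that component correlated across genes with transcript length (Spearman's rho -0.423) and GC content (0.283); genes are not independent replicates. With the GC and length offsets, the treatment split called 272 genes and that split 94. For gene lists, the treatment split called 14 and the highest other split 9, so 1 of the 10 splits gave 14. With 10 splits no share can fall under 0.05.

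The fall of the MAPK output genes was set against 2 technical explanations. A trend with GC content and length argues for a median near 0 once offsets remove it, but the median was -0.247 (bootstrap SE over genes 0.047; camera, adjusted p = 3.42e-10). A single library as the source of the median is argued against by refits without each of the 6. The median nearest 0 was -0.206 (SE 0.07, without PQ replicate 3), and the largest camera adjusted p was 1.28e-05. Genes of a list are not independent, so these errors are too small. With an estimated correlation, which was not used in the refits, the camera adjusted p for all 6 libraries was 0.181. With the preset correlation, camera called 2 to 9 lists in the other splits, so its p alone decides little. Single calls moved with the library left out: edgeR's 5 became 0 without PQ replicate 1, PQ+SS-31 replicate 2 or PQ+SS-31 replicate 3. The log2 fold changes moved less. Over the 6 refits they ranged from -1.05 to -0.98 for DUSP5 and from -0.89 to -0.79 for JUN. They ranged from -0.89 to -0.78 for DUSP6 and from -0.66 to -0.55 for EREG. Refits have fewer libraries, so a lost call does not by itself show a smaller change. No biological explanation was tested: whether SS-31 altered MAPK activity needs phosphorylated ERK, JNK and p38, which were not measured here. With 10 splits a grouping of the samples by chance remains open.

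The rise of cell cycle genes was treated in the same way. With the offsets the G2/M median was 0.462 (SE 0.02; camera, adjusted p = 1.01e-26), and without 1 library the median nearest 0 was 0.394 (SE 0.045, without PQ replicate 3; largest camera adjusted p 5.62e-15). In those refits edgeR called 0 G2/M genes, apart from 11 without PQ replicate 3, against 7 with all libraries. A build-up of cells in G2/M alone was taken to leave G1/S genes near 0, and their median was 0.306 (SE 0.021). That prediction was assumed, and transcript levels per phase were not measured, so the value cannot exclude such a build-up. The SEs here are bootstrap values over genes that are not independent, so they are too small. Whether the share of cycling cells differed was not tested, since it needs cell counts or DNA content, which were not analysed here. The histone list had a median of -0.31, but its call was lost without PQ replicate 3 (median -0.16; camera, adjusted p = 0.0883), the library with its highest level, and with an estimated correlation (adjusted p = 0.478), so it decides little. With 10 splits a grouping of the samples by chance remains open.

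NR1D1 fell by 1.04 on the log2 scale, and 8 clock genes that peak with it had a median of -0.512, from -1.28 for CIART to 0.15 for PER1, with -0.63 for NR1D2, -0.65 for PER3 and -0.02 for PER2; none of the 8 passed the threshold. A difference in clock phase may be the source, in which case genes that peak opposite to NR1D1 should be higher. The median of ARNTL, CLOCK, NPAS2 and NFIL3 was -0.239 with a bootstrap SE of 0.14, so it did not lie above 0, but the spread over 4 genes is too wide to decide.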
